A study of Homo sapiens with 4 samples.

How the data were processed

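RNA-seq libraries of VCaP cells were compared after transfection with a non-targeting control siRNA (siNTC) or with an siRNA against ZBTB7A (siZBTB7A). VCaP is a human prostate cancer cell line that carries a TMPRSS2-ERG fusion. Each group was represented by 2 count tables, numbered as replicates 1 and 2. The labels do not say that the replicates came from separate cultures or transfections. Per the labels' protocols, cells were grown with serum, RNA was extracted on columns, and libraries were made with a stranded total RNA kit.

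Each table held whole-number read counts per gene as deposited by the authors, with no normalization. The tables had the layout of STAR gene counts, with an unstranded count and a count for each strand. STAR 2.4.2a and the genome builds hg19 and GRCh37 are named in the submitters' processing notes. The annotation release is not given in the sources used here. Reads that overlap more than 1 gene or map to several places are kept out of the gene counts in this layout, so genes with near-identical copies are undercounted. The annotation used here was GENCODE 29, which is on another build, so no coordinates are reported. It served for the GC content and length of each gene's longest annotated transcript, which need not be the one expressed. Beyond that it gave only gene names and gene classes. Of 60308 gene identifiers per table, 55698 were named this way by their Ensembl number and 4610 were not. The unnamed identifiers held between 2.01% and 2.28% of gene reads.

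The strand of the kit was chosen by a rule set before the data were examined. The count on the main strand had to exceed that on the other strand by over 5 times, and it did so by 24.9 to 25.5 times in the 4 tables. The 4 rows that name no gene (unmapped, multi-mapping, no annotated exon on the main strand, ambiguous) were left out of library sizes and tests. They held between 50.8% and 51.2% of the reads in each table. The gene reads on the main strand numbered 5737738 and 5927656 in the siNTC tables and 5556061 and 5745862 in the siZBTB7A tables.

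Before any averaging, the 2 tables of each group were compared by a chi-square test of their counts over genes. The agreement found there (given with the results) led to the 2 tables of a group being counted as 1 library. The planned test was kept: edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test in its robust form, TMM factors, filterByExpr, group as the only term, and a Benjamini-Hochberg adjusted p under 0.05. It tested 12848 genes. Because the tables of a group count as 1 library, that test compares 2 libraries and not the 2 conditions, and no p-value here measures biological spread. A gene is called higher or lower below where it passed this test, which means that it differed between the 2 libraries beyond counting error. Folds were computed from the summed tables of each group, scaled by the TMM-adjusted totals, with exact (Clopper-Pearson) 95% intervals. These intervals cover counting error only. CPM values are scaled to the TMM-adjusted gene reads.

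The rule for the genes named was set before the data were examined. It took ZBTB7A, ERG, KLK3 and 1 gene that is not reported here in any case. It took the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the test, with a mean of at least 5 CPM and no overlap between the groups' tables. It also took the 10 such genes with the smallest p, 4 members of each gene list past the set test, and up to 2 called members of each other list. This gave 70 genes. The 26 gene lists were fixed at the same time and held 616 entries. Of these, 612 were matched, 10 of them through a RefSeq synonym, and 4 were not matched. The set test was camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over the 23 lists with at least 5 tested members. Because there is 1 library per group, each list is described mainly by the percentile of its median fold among the medians of 10000 random lists of the same size matched on mean expression. A version matched also on transcript GC content and length was added after the data were seen.

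The alternatives set beforehand were DESeq2 size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at a mean of 1 CPM, unstranded counts, protein-coding genes only, the replicate number as a block, leaving out each table, a minimum fold of 2, a test against a fold of 1.2, and camera with an estimated correlation. Those added after the data were seen were an exact binomial test of the summed tables, edgeR's exact test with an assumed replicate CV of 10% or 20%, DESeq2 without independent filtering, and a correction of the folds by a spline on GC content and length. Of the tested genes, 99.5% had a GC and length value. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

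The test was checked on simulated counts drawn from the real means and library sizes, with 12664 genes tested. Of the genes set 25% higher, or lower by the inverse of that factor, it found 52.2%. It found 82.1% of the genes changed by 1.5-fold and 97% of those changed by 2-fold, and called 0.12% of the unchanged genes. The simulated counts held counting noise only, with no variation between libraries. These shares therefore do not give the rate of false calls in the real comparison of 2 libraries. Of 100 random lists, 4 fell outside the middle 95% of their matched random lists. Those 100 lists were drawn from all tested genes without regard to shared regulation. The check therefore does not cover lists whose members vary together, for which an extreme percentile can arise more often.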

Results

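Gene expression was measured by RNA-seq in VCaP cells transfected with siNTC or siZBTB7A, to ask which genes depend on ZBTB7A, a zinc finger transcriptional repressor. The 4 tables held 11675008 and 12048199 reads for siNTC and 11381794 and 11768355 reads for siZBTB7A. Reads counted in genes came to 11665394 in the summed siNTC tables and 11301923 in the summed siZBTB7A tables.

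The 2 tables of each group differed by no more than the noise of read sampling. Over genes with at least 20 summed reads, chi-square per degree of freedom was 0.993 in siNTC (12762 genes, p = 0.722) and 0.995 in siZBTB7A (12645 genes, p = 0.659). Between tables of different groups it ranged from 3.50 to 3.64. Among the deepest genes, with at least 10000 summed reads, it was 1.53 over 63 genes in siNTC and 1.28 over 59 genes in siZBTB7A. The agreement was therefore not complete in siNTC, where the chi-square test gave p = 0.00452. The replicate CV from edgeR's common dispersion was 0.988%. The 2 tables of each group were therefore counted as 1 sample, and the comparison rests on 1 library per group with no replicate check.

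**Figure D1:**
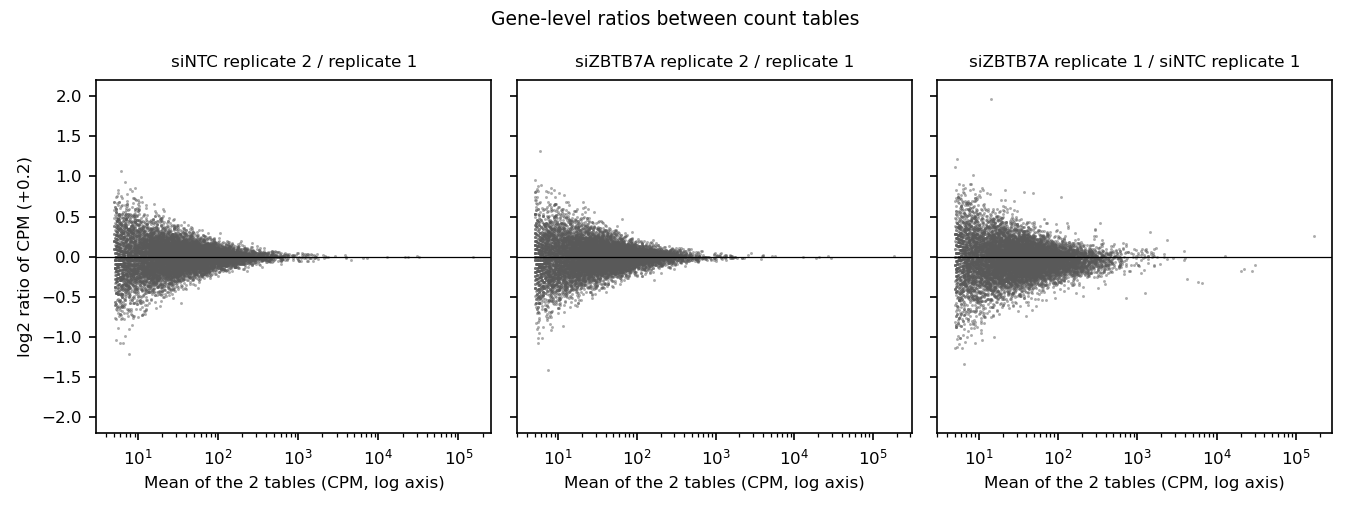
Each point is a gene with a mean of at least 5 CPM. The x axis is the mean CPM of the 2 tables (log axis) and the y axis the log2 ratio of their CPM after adding 0.2, within siNTC, within siZBTB7A, and between the first tables of the 2 groups. The ratios within a group narrow with depth as sampling noise does, and those between groups stay wider at high CPM.

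ZBTB7A itself was counted with 90 and 115 reads in the siNTC tables and 70 and 74 reads in the siZBTB7A tables. This gave 17.4 CPM and 13.0 CPM, a fold of 0.743 with a 95% counting interval of 0.597 to 0.924. The point estimate lay below 1 in the library labelled siZBTB7A, but the gene did not pass the planned test (log2 fold -0.43, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0969). Without the first or the second siNTC table its log2 fold was -0.57 or -0.26. Within counting error, its RNA in the siZBTB7A library was not below 0.597 of the control. The depth at this gene leaves the size of any knockdown within the interval poorly determined.

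Differences between the 2 libraries were numerous but small. Of 12848 genes tested, 289 were higher and 350 lower in the siZBTB7A library, 639 in all. The median fold was 1.198 among the higher genes and 0.841 among the lower ones, and 561 of the 639 (87.8%) lay within 1.5-fold. Among 5372 protein-coding genes at 30 CPM or more, the SD of the log2 fold was 0.124, where counting alone would give 0.077, and 2 genes lay beyond 1.5-fold. This spread beyond counting corresponds to 4.8% per library. If replicate cultures varied by a CV of 10%, an assumption made after the data were seen, 1 gene would pass, and at 20% none would (0 genes), but both CVs exceed the spread measured here. DESeq2 passed 85 genes. Mitochondrial genes took 20.2% of gene reads in the siZBTB7A library and 17.1% in the siNTC library. Most of these were reads of the rRNA MT-RNR2, at 18.4% and 15.4%. Mitochondrial protein-coding genes took 0.518% and 0.437%.

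The largest rises among protein-coding genes with a mean of at least 5 CPM were mostly in genes of low abundance. BRINP1, a neuronal gene, was 1.79-fold higher (1.39 to 2.33), and TMEM238 was 1.78-fold higher (1.49 to 2.13). DDC, which encodes aromatic L-amino acid decarboxylase, was 1.75-fold higher (1.42 to 2.17). F3, which encodes tissue factor, was 1.70-fold higher (1.27 to 2.28), and PLXNB3, a semaphorin receptor gene, was 1.62-fold higher (1.34 to 1.96). NT5M, HMX1, UNC5A and IDUA were higher by 1.69, 1.68, 1.68 and 1.61 times. Among well-counted genes, PPP1R14B, which encodes an inhibitor of protein phosphatase 1, was 1.39-fold higher (1.33 to 1.45) and IGFBP2 1.28-fold higher (1.22 to 1.34). RACK1, a component of the small ribosomal subunit, was 1.08-fold higher (1.068 to 1.096).

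The largest falls under the same limit were in genes with few reads. CLCN5, which encodes an endosomal chloride-proton exchanger, was at 0.451 of the control level (0.308 to 0.650) from 101 and 43 reads. IGIP stood at 0.488 (0.347 to 0.680). PRKCE, which encodes protein kinase C epsilon, stood at 0.569 (0.432 to 0.746). RHOBTB1, MSTO1, NPRL3, ZNF239, ZNF354C, SEC61A2 and HELB were at 0.572, 0.576, 0.585, 0.594, 0.597, 0.608 and 0.619 of the control. MSTO1 has a near-identical pseudogene copy, so its count is uncertain. TP53INP1, a p53 target, was lower with far more reads, at 0.793 (0.757 to 0.830), from 4288 and 3213 reads.

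**Figure D2:**
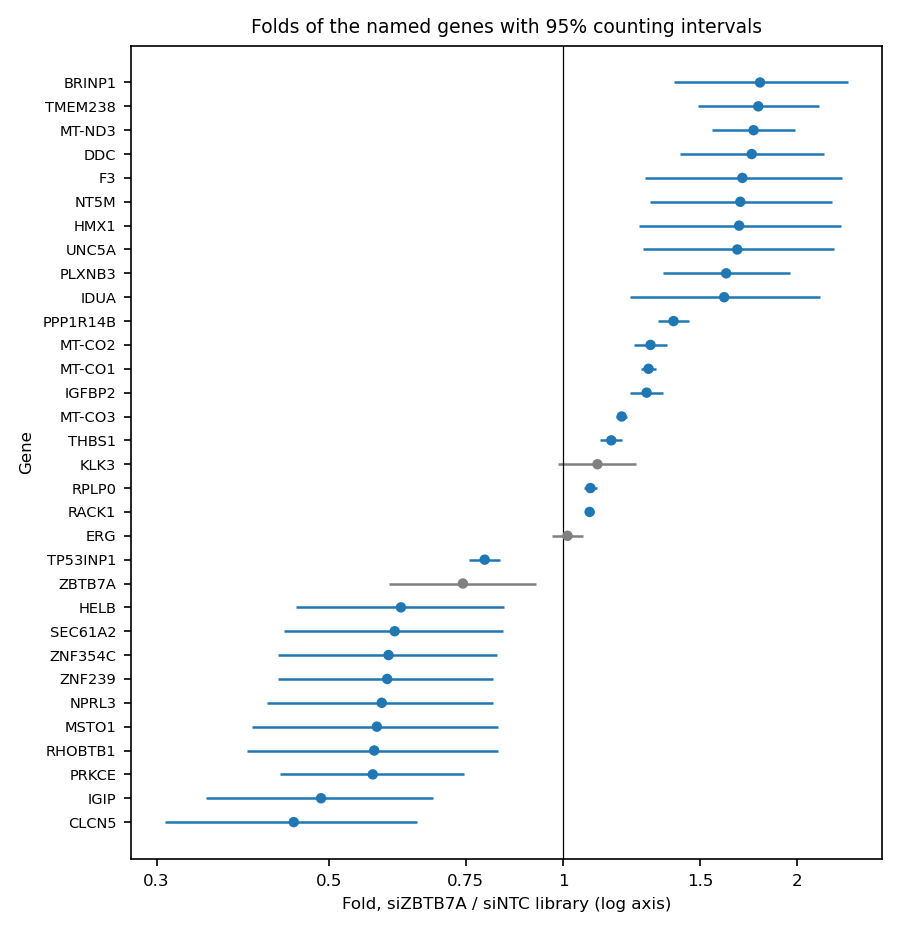
Folds of the siZBTB7A over the siNTC library (x axis, log axis) for the genes named by size of change, by smallest p or in any case, each a point with its 95% counting interval. Blue genes passed the planned test and grey genes did not: ZBTB7A at 0.743, ERG at 1.01 and KLK3 at 1.11.

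Androgen signalling genes showed no common direction. ERG, the oncogenic transcription factor expressed from the fusion, was at 1.01 (0.967 to 1.06), and KLK3, which encodes prostate-specific antigen, at 1.11 (0.987 to 1.24). Of 22 tested androgen-induced genes, 2 were higher and 1 lower (2 and 2 adjusted over the list alone), with a median fold of 1.004. The higher ones were SLC45A3 at 1.16 (1.099 to 1.21) and KLK2 at 1.024 (1.010 to 1.037), and with the GC and length correction KLK2 was no longer higher (log2 fold -0.002). NDRG1 was lower at 0.952 (0.933 to 0.972). Of 14 androgen-repressed genes, 2 were higher and 0 lower (3 and 1 adjusted over the list alone), namely DDC and CAMK2N1 at 1.22 (1.12 to 1.34). In the list of ERG-induced genes, 1 of 15 was lower, TDRD1 at 0.903 (0.8586 to 0.9503), and the median log2 fold of 0.03 and the mean of -0.02 differed in sign.

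Genes reported to be repressed by ZBTB7A did not move together. Of 8 tested, 1 was higher, MCAM, a cell adhesion gene, at 1.54 (1.34 to 1.77) (1 adjusted over the list alone). The median fold of the list was 1.016, at the 66.2 percentile of matched random lists. ZBTB7A itself did not pass the test (fold 0.743, 0.597 to 0.924), so this list was read without an established knockdown.

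A majority of the cytosolic ribosomal protein genes were slightly higher. Of 40 tested, 24 were higher and 0 lower (27 and 0 adjusted over the list alone), and 38 had a fold above 1. RPL27 was at 1.136 (1.102 to 1.172), RPLP1 at 1.11 (1.08 to 1.15), RPLP0 at 1.08 (1.06 to 1.11) and RPS6 at 1.049 (1.031 to 1.068). The median fold was 1.052, above all 10000 matched random lists (percentile 100). In the planned camera test between the 2 libraries the adjusted p was 0.00141, and adjusted p = 0.676 with an estimated correlation. Ribosomal protein genes share sequence with many pseudogenes, so their unique read counts are uncertain. The higher genes as a whole had shorter and more GC-rich transcripts than the lower ones, with a median of 54.2% GC and 2975 bases against 41.2% and 7543 bases.

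The joint list of Notch and Wnt target genes also stood high, but none of its Wnt targets was called. Of 8 tested, 2 were higher (3 adjusted over the list alone), NRARP at 1.42 (1.18 to 1.71) and HES4 at 1.35 (1.15 to 1.58), both Notch targets. With the GC and length correction neither passed, at folds of 1.27 and 1.12. HES1 at 1.33 (0.952 to 1.87) and NOTCH3 at 1.33 (1.099 to 1.61) did not pass. The list median was 1.24 (1.14 with that correction), at percentile 100, with a camera adjusted p of 0.0138 and adjusted p = 0.676 with an estimated correlation. The list was no longer past the set test without a low-count filter (adjusted p = 0.0571) or with unstranded counts (adjusted p = 0.139).

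Lists of mitosis and stress response genes stood low. Of 34 mitosis genes, 5 were lower and 1 higher (7 and 1 adjusted over the list alone), with a median fold of 0.958 at the 0.3 percentile. TOP2A, which encodes topoisomerase II alpha, was at 0.888 (0.860 to 0.916) and CENPF, a kinetochore gene, at 0.881 (0.835 to 0.929). Of 26 genes of the unfolded protein and integrated stress response, 6 were lower and 0 higher (7 and 0 adjusted over the list alone), with a median log2 fold of -0.07 at the 0.6 percentile. The chaperone genes HSP90B1 and CALR were at 0.905 (0.883 to 0.927) and 0.952 (0.933 to 0.972). Of 13 paralogs of the ZBTB family, 2 were lower (2 adjusted over the list alone), with a median of 0.927 at the 0.5 percentile, ZBTB10 at 0.869 (0.828 to 0.913) and ZBTB4 at 0.749 (0.624 to 0.899). None of these 3 lists passed the camera test (adjusted p = 0.235, 0.138 and 0.166). Of the 25 lists with a percentile, 5 lay outside the middle 95% of matched random lists. With lists matched also on GC content and length it was 4, and the ZBTB family list was then inside, at the 3.0 percentile.

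The metabolic, hypoxia, DNA replication and histone lists lay inside the middle 95% of their random lists. Of 42 nuclear-encoded oxidative phosphorylation genes, 5 were higher (6 higher and 1 lower adjusted over the list alone), with a median of 1.03 at the 96.0 percentile, among them the ATP synthase subunit genes ATP5F1C at 1.124 (1.052 to 1.202) and ATP5F1B at 1.046 (1.025 to 1.068). Of 15 hypoxia genes, 4 were lower (4 adjusted over the list alone), at the 6.3 percentile, including ERO1A at 0.815 (0.724 to 0.917). Of 22 glycolysis genes, 1 was higher, LDHB at 1.096 (1.067 to 1.126), and 1 lower, PDK1 at 0.867 (0.796 to 0.945), the same count adjusted over the list alone, at the 20.8 percentile. Of 52 DNA replication genes, 2 were higher and 1 lower (2 and 2 adjusted over the list alone), at the 16.1 percentile, among them the transcription factor gene E2F1 at 1.23 (1.12 to 1.36) and the DNA ligase gene LIG1 at 0.819 (0.724 to 0.927). Of 30 cholesterol and fatty acid synthesis genes, 2 were higher and 2 lower (2 and 3 adjusted over the list alone), at the 70.0 percentile, with FASN at 1.087 (1.0475 to 1.128) and ACACA at 0.924 (0.895 to 0.953). Of 20 histone genes, 2 were higher (2 higher and 1 lower adjusted over the list alone), at the 54.0 percentile, HIST1H1E at 1.09 (1.07 to 1.12) and HIST1H2BD at 1.07 (1.03 to 1.13).

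The other response lists also lay inside the range of their random lists. Of 25 p53 targets, 1 was lower, TP53INP1 (1 adjusted over the list alone), at the 65.9 percentile. Of 17 interferon-stimulated genes, 0 were called (0 adjusted over the list alone), at the 47.5 percentile. Of 14 NF-kB targets, 1 was higher (2 adjusted over the list alone), NFKBIA at 1.252 (1.112 to 1.411), at the 80.3 percentile. Of 8 immediate early genes, 1 was higher (2 adjusted over the list alone), JUND at 1.1495 (1.0538 to 1.2541), at the 91.6 percentile. With the GC and length correction the fold of JUND was 1.0008. Of 21 autophagy and lysosome genes, 1 was higher (1 adjusted over the list alone), SQSTM1 at 1.1004 (1.0345 to 1.1704), at the 87.9 percentile.

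The medians of the cell identity lists that could be tested lay inside the same range. Of 14 luminal markers, 2 were higher (4 higher and 2 lower adjusted over the list alone), FOLH1, which encodes prostate-specific membrane antigen, at 1.16 (1.11 to 1.21) and HOXB13 at 1.08 (1.04 to 1.13), at the 92.0 percentile. Of 3 tested basal markers, 1 was lower (3 adjusted over the list alone), DST at 0.910 (0.862 to 0.961), at the 11.4 percentile, and with the GC and length correction its log2 fold was 0.02. Of 5 tested genes of the epithelial-mesenchymal transition list, 2 were higher (2 adjusted over the list alone), TAGLN at 2.47 (1.39 to 4.56) from 18 and 42 reads and THBS1 at 1.15 (1.12 to 1.19), at the 91.4 percentile. Of 11 neuroendocrine markers and 3 fibroblast markers, 0 were called (0 adjusted over the list alone), at the 45.3 and 14.8 percentiles. The neuroendocrine list had a median log2 fold of -0.01 and a mean of 0.001, which differed in sign. The 13 leukocyte and endothelial markers together had 10 and 13 reads, and none (0) was abundant enough to test.

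With the correction for GC content and length, which was added after the data were seen, 24 of the named genes no longer passed the test and 2 more, KLK2 and DST, changed sign. For 6 of the 24 the fold hardly moved and the adjusted p, at 0.0294 to 0.045 before, was 0.0514 to 0.0724 after: RHOBTB1 went from 0.572 to 0.571, SEC61A2 from 0.608 to 0.600, ZBTB4 from 0.749 to 0.747, ZNF354C from 0.597 to 0.618, TAGLN from 2.47 to 2.39 and HIST1H2BD from 1.075 to 1.073. In E2F1, ERO1A, HELB, HMX1, HOXB13, IDUA, NRARP, SQSTM1, TDRD1 and UNC5A the corrected fold was nearer to 1 but still within the counting interval of the uncorrected one, which gives 16 such genes with the 6 above. In the remaining 8 it lay outside that interval, nearer to 1: ACACA, ATP5F1B, CENPF, FASN, HES4, JUND, PDK1 and ZBTB10. Some named genes that still passed also had a corrected fold outside that interval and nearer to 1. PPP1R14B went from 1.387 to 1.246, TMEM238 from 1.783 to 1.490 and RACK1 from 1.082 to 1.054. RPLP0 went from 1.085 to 1.057, HIST1H1E from 1.091 to 1.061 and TOP2A from 0.888 to 0.923. CALR, from 0.952 to 0.926, and THBS1, from 1.154 to 1.193, left the interval away from 1.

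**Figure D3:**
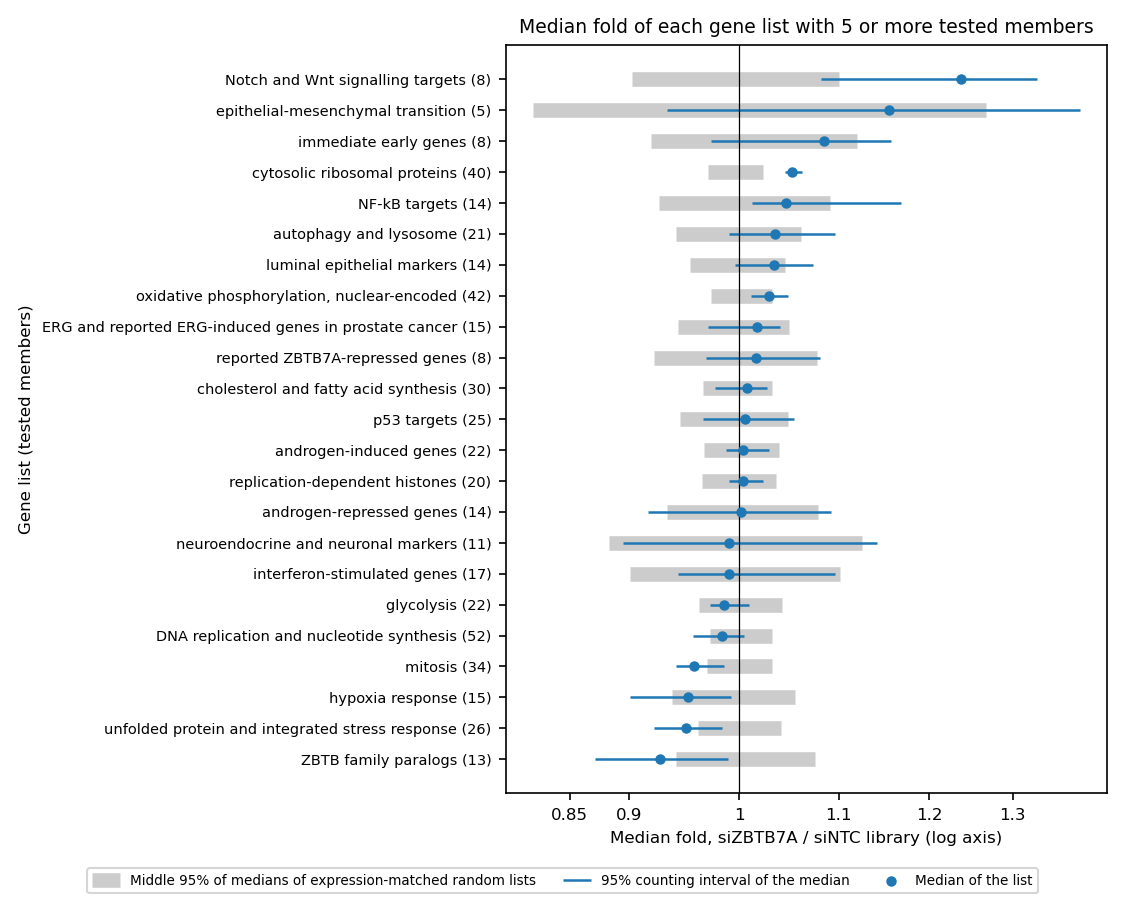
Median fold of each list with at least 5 tested members (x axis, log axis; number of tested members in brackets), as points with 95% counting intervals. Grey bars show the middle 95% of the medians of expression-matched random lists. The ribosomal protein list at 1.052 and the Notch and Wnt list at 1.24 lie above their bars.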

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

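The reads at no annotated exon on the main strand can include intronic and opposite-strand reads of annotated genes. These reads, which no comparison above uses, took a larger share of the siZBTB7A library than of the control. The share was 23.149% (exact 95% interval 23.132% to 23.166%) against 20.594% (20.578% to 20.611%) in siNTC. Both siZBTB7A tables, at 23.13% and 23.17%, lay above both siNTC tables, at 20.58% and 20.61%. Multi-mapping reads went the other way, at 22.240% against 24.419%. These intervals cover counting error only, and with 1 library per group neither difference has a replicate check.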

How the results depend on the processing

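The assumed CVs, the exact binomial test, DESeq2 without independent filtering and the GC and length correction were chosen after the data were seen. The count of 639 genes (289 higher, 350 lower) stayed within 1.5 times with DESeq2 size factors (650), limma-voom (541), a filter at a mean of 1 CPM (650), no filter (502), unstranded counts (647), protein-coding genes (596) and the exact binomial test (651). Deviations of same-numbered tables correlated at -0.015 over 5461 genes. Where tables of a group differ by counting noise, this correlation would be small in any case, so it does not show what the numbers share. Gene reads of replicate 2 over replicate 1 were 1.033 in siNTC and 1.034 in siZBTB7A, and the reason was not tested. The replicate block called 654 genes (297 higher, 357 lower). DESeq2 called 85 (41 higher, 44 lower), of which 83 were among the 639, and gave no adjusted p for 11707 genes, 380 of the 639 among them. Without independent filtering it called 58 (30 and 28), so that filter did not produce the low count, and the cause was not tested. A minimum fold of 2 left 29 (14 and 15) and a test against a fold of 1.2 left 11 (8 and 3), as stricter criteria do. With an assumed replicate CV of 10%, 1 gene passed (1 higher, 0 lower), and with 20%, 0 passed (0 higher, 0 lower). The GC and length correction left 371 (188 and 183), of which 301 were among the 639. Leaving out a table called 303 to 373 genes (141 to 165 higher, 162 to 217 lower): 373 without siNTC 1, 353 without siNTC 2, 346 without siZBTB7A 1 and 303 without siZBTB7A 2. With the tables of a group counted as 1 library, such a step only lowers that group's reads and is no independent replicate.

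The target ZBTB7A stayed below the threshold in each alternative that gave it an adjusted p, with log2 folds from -0.57 to -0.26. Of the 2 lists past the set test, 1 remained without a low-count filter and 1 with unstranded counts, 0 with an estimated correlation, and 0 to 2 when a table was left out (0 without siNTC 1 and 0 without siZBTB7A 2). Of 253 set test values, 245 kept their side of the threshold and 8 lost it. Of 1224 values for the 70 named genes, 819 kept their side, 393 fell short, 9 newly passed and 3 reversed. The reversals were DST (log2 fold 0.023) and KLK2 (-0.002) under the GC and length correction, and ERG without siZBTB7A 1 (range over the left-out tables -0.026 to 0.065). The cause of the ERG reversal was not tested, and its fold was within counting error of 1. Of 324 list medians, 318 stayed within their counting interval and 6 moved. Depth limits the low genes most, as the interval of ZBTB7A shows.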

Other observations

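The gene groups in this part were chosen after the data were seen, as were the tests that weigh the 3 patterns; for 2 of these tests the expected outcome was written before their result was known, namely the matching of the ribosomal list on GC content and length, and the correction of the folds of the called mitochondrial genes. Of 13 mitochondrially encoded protein genes, 6 were higher and 0 lower in the siZBTB7A library, and 7 did not pass the test. The median fold of the 13 was 1.19, above all 10000 matched random lists. MT-ND3 stood at 1.76 (1.56 to 1.99), MT-CO2 at 1.296 (1.235 to 1.360), MT-CO1 at 1.29 (1.26 to 1.32) and MT-CO3 at 1.19 (1.17 to 1.21), whereas MT-ND1 was at 1.019 (0.9496 to 1.093) and MT-ND5 at 0.941 (0.8499 to 1.042), neither past the test. The mitochondrial rRNA MT-RNR2 took 18.427% of gene reads against 15.385%. Its fold, which is scaled by the TMM-adjusted totals and so is not the ratio of these shares, was 1.228 (1.2255 to 1.2304). The other mitochondrial rRNA, MT-RNR1, was at a fold of 1.03 (1.026 to 1.041).

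Of 42 small nucleolar RNA genes, 8 were lower and 0 higher, and 34 did not pass the test; 13 had a fold above 1. The median fold of the 42 was 0.836, at percentile 0 of matched random lists, and 0.896 with the GC and length correction. SNORA73B was at 0.705 (0.684 to 0.728), and its host gene SNHG3 at 0.745 (0.728 to 0.763). Reads of a snoRNA and its host cannot be fully told apart, and short RNAs are poorly captured by such libraries. MIR3648-2, annotated as a microRNA gene, was the 1 gene past the test with an assumed CV of 10%. It stood at 3.56 (2.74 to 4.68) from 74 and 249 reads. It has near-identical copies, so its count is uncertain. MIR3687-2, of the same class, was at 1.82 (1.67 to 1.97) from 920 and 1579 reads. It was among the 8 genes higher in the test against a fold of 1.2, where 3 were lower. Whether the reads of these 2 genes come from microRNA precursors or from other RNA was not tested. Mitochondrial ribosomal protein genes had a median of 1.04 over 77 genes, at the 99.8 percentile, or 94.7 when lists were matched also on GC content and length, and the corrected median was 1.024. Zinc finger genes named ZNF had a median of 0.970 over 432 genes, at the 0.0 percentile, or 0.4 with that matching, and the corrected median was 0.984. Of the 7 groups looked at, the remaining 3 lay inside the range of their random lists: snRNA genes at the 14.6 percentile (3 of 14 lower), lincRNA genes at 54.2 (5 higher and 9 lower of 256) and antisense genes at 16.7 (6 of 327 lower).

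The first pattern is the many small differences between the libraries. Repeat sequencing of 1 library per group is a candidate explanation for the small spread the test saw: chi-square per degree of freedom within a group was at most 0.964 in genes with 1000 or more reads, although it reached 1.53 in the deepest siNTC genes. GC content and length as the whole cause is argued against only as far as the spline captures such a bias. After the correction 371 genes were still past the threshold, 301 of them among the original 639. The spline accounted for 9.4% of the variance of the log2 folds over genes at 5 CPM or more. That variance includes counting noise, so the spline's share of the differences beyond counting was not determined. A bias that it missed would leave calls too. Log2 folds did correlate with GC content (Spearman's rho 0.335) and length (-0.326) across well-counted genes, which are not independent replicates. Ordinary variation between separately made libraries cannot be told apart from an effect of the siRNA, since there is 1 library per group; the 1 gene past the test with an assumed CV of 10% decides nothing, because that CV exceeds the whole spread beyond counting (4.8% per library).

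The second pattern is the ribosomal protein list. GC content and length of the longest annotated transcripts, as its cause, are argued against. The list's median lay above all matched lists (percentile 100) also when these were matched on those values. Those transcripts had a median length of 1917 bases in this list and need not be the ones expressed. A bias by the length of the expressed transcripts was therefore not tested. The median fold was 1.052 before the correction and 1.038 after it. Variation between libraries and an effect of the siRNA both stay open, and neither was tested.

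The third pattern is the mitochondrial mRNAs. A single factor for all mitochondrial RNA as the whole cause is argued against, since the folds of the 13 genes differed among themselves by more than counting error plus the general spread beyond it (SD 0.097 on the log2 scale): chi-square per degree of freedom was 4.12, at percentile 100 among 10000 sets of nuclear genes matched on expression, and 2.60, at the 99.5 percentile, without MT-ND3. For GC content and length, the median fold of all 13 genes was 1.2 after the correction (counting interval 1.151 to 1.254). Over the called genes alone, which were picked for their rise, it was 1.265. The spline was fitted without mitochondrial genes. These values therefore argue against such a bias only as far as the pattern of nuclear genes holds for mitochondrial ones, which was not tested. A difference between the libraries in RNA handling and an effect of the siRNA both stay open, and neither was tested.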
